A study of Caenorhabditis elegans with 4 samples.

How the data were processed

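COH-1 ChIP-seq was performed on adult hermaphrodite worms of the fem-2(b245) strain. Per the labels' protocols, ground frozen worms were crosslinked with EGS, a protein crosslinker, and then with EGS and formaldehyde together. Chromatin was sheared by sonication, COH-1 was recovered with a rabbit polyclonal antibody and protein A or G beads, and single-end Illumina libraries were made after PCR. The labels give 4 libraries, 2 of ChIP DNA and 2 of input DNA, each pair numbered as replicates 1 and 2. Processed files of the 2 ChIP libraries were used, and the input libraries were not analysed here. Groups and replicate numbers were taken from the sample titles.

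Reads were aligned with BWA to ce10, per the submitters' processing notes. Peaks were called with MACS on WormBase build WS220, per the file headers and the source column of the deposited lists. There was 1 list per ChIP library, so peaks were not called on pooled replicates. The versions, the peak threshold, the control used in calling and any filter are not given in the sources used here. The deposited score of each peak is the value MACS attached to it, whose scale the files do not name. It was used to describe, rank and filter peaks within a list, and the ranks were compared between lists over shared intervals. The smallest score was 50.04 in replicate 1 and 50.07 in replicate 2, and many of the strongest peaks shared the value 3100. The lists give no read counts, so depth is unknown and no interval or detection limit based on reads is given. Intervals on shares of peaks are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only. The names under which the lists were deposited carry tags that occur nowhere in the labels, BC299 for replicate 1 and csr1 for replicate 2. What the tags mean is not stated, and each list was taken as belonging to the sample it was deposited with.

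Overlaps were computed with bedtools 2.31.1, and all other values with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. Peaks linked by such overlaps were joined into a shared interval, with the best score of each list. Chance overlap was measured by circular shifts of 1 list along each chromosome, with 2000 shifts per chromosome combined at random into 100000 resamples. Strongest and weakest peaks were compared over 10 equal classes of each list by score, and between its upper and lower 50%. Chromosome lengths were taken from base 1 to the last peak of either list (99.998 Mb in all), since no sequence of build WS220 was used. The number of peaks on X was tested against its share of that length, and the number of midpoints in the centre (the middle 33.3% of each length) against 33.3%, with exact binomial tests. Neighbours were counted within 10 kb and compared with 10000 even placements of the midpoints. Correlations were computed across intervals or 500 kb bins, with 100000 permutations. All tests were two-sided, with a threshold of 0.05. Adjusted p-values follow Benjamini-Hochberg over the 6 chromosomes within each set of peaks.

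The intervals named in the text follow a rule set before the data were examined: the 25 shared intervals with the best mean rank in the lists, and the 3 strongest peaks of each list without a partner. The bins, merged sites and peak-free stretches named in the text were picked by size after their values were seen. Alternatives set before the data were examined were the stronger 50% of each list, each list alone, a reciprocal overlap of 50%, midpoints within 500 bp, equal list lengths, the middle 50% in place of the middle 33.3%, intervals with 1 peak of each list, and neighbours within 5 kb. Alternatives added after seeing the data were merging of peaks within 5 or 10 kb, length from the first to the last peak, exclusion of scores of 3100 or more, the strongest 10% of each list, and local shifts of 20 to 100 kb.

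Planned comparisons of peaks with promoters, exons and introns, with 11 fixed gene lists, with classes of non-coding RNA genes and at coh-1 itself were not made. The gene table at hand is of assembly WBcel235, not of the build of the peak lists, and coordinates of different builds were not combined. The computations were tested on simulated lists of about the same size as the real ones. With 60% of peaks planted as shared, 61.6% were found as overlapping. Of 100 pairs of independent lists, 9 gave an overlap p under 0.05, which is more than that threshold implies. These runs used fewer shifts and resamples than the test of the real lists, and drew all peak widths from replicate 1. An X ratio planted at 1.5 was estimated at 1.51 on average, and 95 of 100 intervals held it. The simulated peaks were placed independently of each other, without the clustering of the real lists. The simulations therefore do not show how well the intervals and p-values hold for clustered peaks.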

Results

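The binding of COH-1 along the chromosomes of Caenorhabditis elegans was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq). COH-1 is a kleisin, the subunit that closes the ring of the cohesin complex, which holds DNA molecules together and shapes chromosome folding. The worms were adult hermaphrodites of a strain that carries the b245 allele of fem-2, a gene of the sex determination pathway. The study comprised 4 libraries: 2 immunoprecipitated with a rabbit polyclonal antibody against COH-1 and 2 made from input DNA. Each ChIP library had its own list of called peaks, with the position and the caller's score of each peak in WormBase build WS220. The input libraries had no peak list and were not analysed here, so no ChIP value is set against a background measured in the same way. The lists carried no read counts, and the sequencing depth behind a peak is unknown. The design implies 2 questions, namely how far the lists of the replicates name the same sites, and where on the chromosomes those sites lie. All statements on spread rest on n = 2 lists. Nothing in the labels says whether the libraries came from separate cultures, so the spread between them may be technical.

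COH-1 peaks lay on all 6 nuclear chromosomes in both lists. Replicate 1 held 2964 peaks over 7.83 Mb, and replicate 2 held 2302 peaks over 5.85 Mb. The mean was 2633 ± 468.1 peaks (SD, n = 2). The median width was 1513 bp in replicate 1 and 1564 bp in replicate 2, with a mean of 1538 ± 36.1 bp (SD, n = 2). A minority of peaks was far broader, up to 33.3 kb in replicate 1 and 28.5 kb in replicate 2. The authors' score started just above 50 in both lists but reached higher values in replicate 2. Its median was 118.97 in replicate 1 and 257 in replicate 2, and 7 peaks of replicate 1 and 144 of replicate 2 scored 3100 or more. Beyond this description, scores were therefore compared by rank only, and 136 of the strongest peaks of replicate 2 were tied at 3100.

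The first comparison asked whether both lists named the same sites. Of the replicate 1 peaks, 1429 overlapped a replicate 2 peak by at least 1 bp, which is 48.2% (exact 95% interval 46.4% to 50.03%). Of the replicate 2 peaks, 1617 overlapped a replicate 1 peak, which is 70.2% (68.3% to 72.1%). When one list was moved around each chromosome by circular shifts, 9.57% of replicate 1 and 12.8% of replicate 2 peaks overlapped on average, so the observed counts were 5.04 and 5.48 times the shifted means. No peak had identical borders in both lists. The overlapping peaks formed 1189 shared intervals with a median width of 3299 bp and a total of 6.07 Mb, and 804 of them held exactly 1 peak of each list. The overlap exceeded all 100000 resampled shifts for both lists (permutation test, two-sided, p = 2e-05, the smallest value the resamples can give). Under a reciprocal overlap of 50% the shares were 27.7% of replicate 1 and 35.6% of replicate 2 peaks, and with midpoints within 500 bp they were 22.6% and 29.1%. Shifted lists gave 2.06% and 2.67% under the first rule and 2.36% and 3.06% under the second.

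The strongest COH-1 sites were found in both lists far more often than the weak ones. In the strongest 10% by score, 279 of 297 replicate 1 peaks (93.9%, exact 95% interval 90.6% to 96.4%) and 223 of 231 replicate 2 peaks (96.5%, 93.3% to 98.5%) overlapped the other list. In the weakest 10% the shares were 22.2% (17.6% to 27.4%) and 50.2% (43.6% to 56.8%). The upper 50% of replicate 1 by score was shared at 66.1% and the lower 50% at 30.3%, a difference of 35.8 percentage points (Fisher's exact test, two-sided, p = 2.1e-86). For replicate 2 these parts stood at 85.4% and 55.1%, a difference of 30.3 points (Fisher's exact test, two-sided, p = 1.17e-58). Strong peaks were also wide: the strongest 10% had a median width of 6714 bp in replicate 1 and 5878 bp in replicate 2, against 1015 bp and 922 bp in the weakest 10%. A wide peak overlaps others more often by chance. Under the reciprocal overlap of 50% the differences between the upper and lower parts were 21.1 and 20.9 points.

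**Figure D1:**
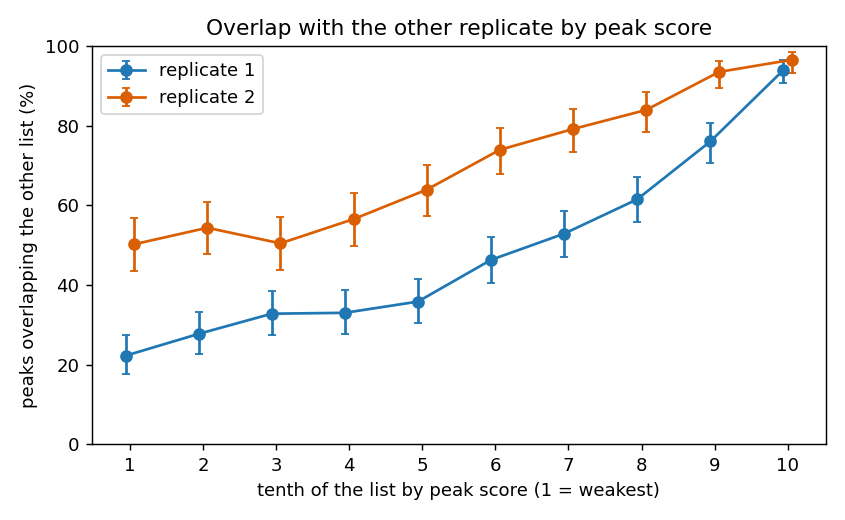
Share of peaks (%) that overlap the other replicate's list by at least 1 bp, against score class (10 equal classes of the list by the authors' score, of which 1 is the weakest), for each replicate; bars are exact 95% binomial intervals, which cover counting error only. The share went from 22.2% in the weakest to 93.9% in the strongest class of replicate 1, and from 50.2% to 96.5% in replicate 2.

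Within the 1189 shared intervals, the ranks of the scores in the lists were positively related across intervals, with Spearman's rho = 0.46 (permutation p = 1e-05, the smallest the resamples can give). Intervals are not independent replicates. The relation was similar on X (rho = 0.44 over 260 intervals) and on the autosomes (rho = 0.47 over 929). Where an interval held exactly 1 peak of each list, rho was 0.30. Without the intervals that scored 3100 or more in either list, rho was 0.36.

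The 25 shared intervals with the best mean rank in both lists were spread over every nuclear chromosome: 7 on X, 5 each on III and V, 3 each on I and IV, and 2 on II. They were 6.43 to 30.3 kb wide, with a median of 12.2 kb. Each scored at least 1638 in replicate 1 and at least 3100 in replicate 2, so that ties in replicate 2 left the order among most of them to replicate 1. The top interval lay on X from 11599807 to 11611823, with scores of 3100 in replicate 1 and 3193 in replicate 2. The next was also on X, from 10565780 to 10572367, with scores of 2278 and 3186. A further 4 intervals scored 3100 in both lists. They lay on II from 11611130 to 11641468, on III from 13051565 to 13067346, on IV from 14029059 to 14038966, and on X from 13138261 to 13150019. On V the highest ranked interval was that from 5836307 to 5847550, with scores of 2879 and 3100. On I it was that from 5303314 to 5322983, with scores of 2036 and 3100. A pair of neighbours near the left end of V, from 1145943 to 1152368 and from 1153064 to 1161664, was also among the 25. The 7 of 25 on X did not differ detectably from the share of X among the other shared intervals (Fisher's exact test, two-sided, p = 0.46). No gene annotation of build WS220 was used here, and these sites are given by position without the genes they cover.

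Some strong peaks overlapped no peak of the other list, although several of them lay close to one. The 3 strongest peaks of replicate 1 without a partner lay on X from 6245104 to 6261524 (score 2763, 5.19 kb from the nearest replicate 2 peak), on I from 11201540 to 11206246 (score 1529, 13.8 kb away) and on I from 10029399 to 10033636 (score 1247, 0.513 kb away). Those of replicate 2 all scored 3100. They lay on II from 9119520 to 9125822, 38.6 kb from the nearest replicate 1 peak, on II from 9284026 to 9290496, 8.61 kb away, and on III from 8790498 to 8796466, 0.258 kb away.

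The next comparison set X, the chromosome under dosage compensation in hermaphrodites, against the autosomes. Counted over whole lists, X carried more COH-1 peaks per length than the autosomes in both, but the excess differed between them and was not seen among the strongest peaks of replicate 2. Replicate 1 had 45.0 peaks per Mb on X and 26.4 per Mb on the autosomes, a ratio of 1.71 (exact 95% interval 1.57 to 1.85). Replicate 2 had 26.6 and 22.3 peaks per Mb, a ratio of 1.19 (1.08 to 1.32). The mean ratio was 1.45 ± 0.36 (SD, n = 2). In the strongest 10% of replicate 1, 24.6% of peaks lay on X, a ratio of 1.52 (1.15 to 1.99; exact binomial test, two-sided, p = 0.0029). In the strongest 10% of replicate 2 the share was 14.3% and the ratio turned to 0.78 (0.52 to 1.13; exact binomial p = 0.196), with an interval that includes 1. By covered length, replicate 1 had most on X, 102.9 kb per Mb, followed by III with 92.5 kb per Mb. Replicate 2 had most on III, 75.9 kb per Mb, with 60.5 on II and 60.3 on X. Among the shared intervals, 260 of 1189 lay on X, or 21.9% against the 17.6% of the length that X takes up. The ratio of shared intervals was 1.31 (1.13 to 1.501; exact binomial test, two-sided, p = 0.00019). Among the autosomes, III had the most shared intervals per Mb, 13.7, and V the fewest, 8.85, beside 14.7 on X. By the covered length of the shared intervals III stood above X, with 77.3 against 66.4 kb per Mb. These tests count every interval as independent, while neighbouring intervals clustered. When shared intervals within 10 kb were merged, the X ratio was 1.20 (0.99 to 1.46; exact binomial p = 0.061), and with only the stronger 50% of each list it was 1.13 (exact binomial p = 0.24). Under either setting the X excess among shared sites kept its direction but did not pass the threshold. The ratio was 1.31 under a reciprocal overlap of 50% (exact binomial p = 0.0016). Over the length from the first to the last peak it was 1.30 (exact binomial p = 0.00022). The last 2 settings still count clustered intervals as independent.

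**Figure D2:**
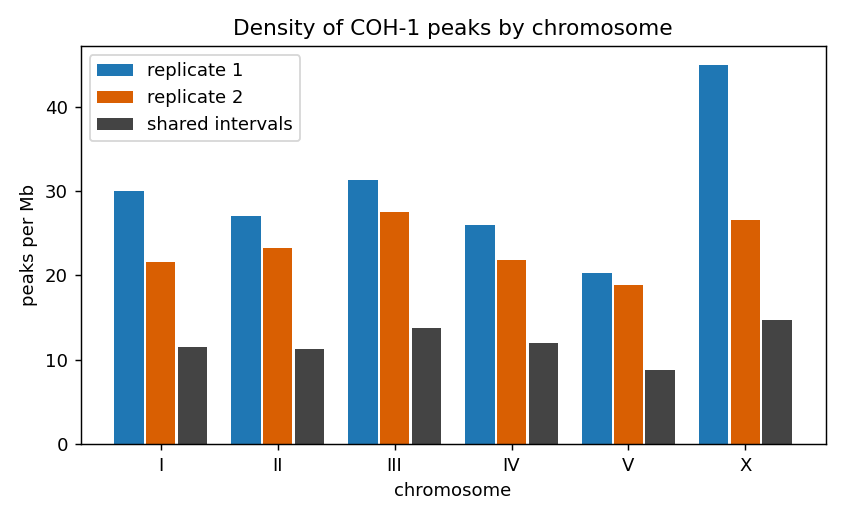
COH-1 peaks per Mb on each chromosome for replicate 1, replicate 2 and the shared intervals (bars, from 0); chromosome length was taken from base 1 to the last peak. X stood highest in replicate 1, at 45.0 peaks per Mb, and among the shared intervals, at 14.7 per Mb, while III was highest in replicate 2, at 27.5 per Mb beside 26.6 on X.

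The lists differed in their share of peaks on X by more than counting error if peaks are taken as independent. It was 26.8% in replicate 1 and 20.4% in replicate 2, with an odds ratio of 1.43 (95% interval 1.25 to 1.63; Fisher's exact test, two-sided, p = 7.65e-08), a test that compares these libraries and not conditions. Peaks clustered and many sites stood in both lists, so this interval and p-value overstate the evidence. After merging peaks within 10 kb the shares were 24.98% and 18.6% (Fisher's exact test, two-sided, p = 0.0011). Both lists were deposited under names with tags that the labels of the libraries do not contain, BC299 for replicate 1 and csr1 for replicate 2. The same difference enters the overlap by chromosome, since similar numbers of X peaks, 304 of 793 in replicate 1 and 359 of 469 in replicate 2, were shared. The shared part was thus 38.3% of X peaks and 51.8% of autosomal peaks in replicate 1, and 76.5% and 68.6% in replicate 2. Circular shifts gave 9.44% on X and 9.62% on the autosomes for replicate 1, and 16.6% and 11.9% for replicate 2. The observed overlap was therefore 4.06 times the shifted mean on X and 5.39 times on the autosomes in replicate 1, and 4.61 and 5.79 times in replicate 2, and the difference between these ratios was not tested.

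COH-1 peaks were concentrated in the centres of the autosomes, taken as the middle 33.3% of the length of each chromosome, and such a concentration was not detected on X. Of the shared intervals, 45.8% had their midpoint in a centre (exact 95% interval 42.9% to 48.6%), where even placement gives 33.3% (exact binomial test, two-sided, p = 8.74e-19). The autosomes alone gave 49.9% (46.7% to 53.2%) and X gave 30.8% (25.2% to 36.8%), a difference between X and the autosomes beyond counting error (Fisher's exact test, two-sided, p = 3.38e-08). Over the lists, the autosomal share was 50.1% ± 2.25 and the X share 32.3% ± 4.97 (SD, n = 2 each). Among the shared intervals, V had the highest central share, 56.0%, and III the lowest of the autosomes, 43.4%. All 5 autosomes exceeded even placement among the shared intervals, with Benjamini-Hochberg adjusted p-values over the 6 chromosomes from 1.93e-09 on V to 0.0050 on III (exact binomial tests). In replicate 2 alone III had 37.7% and did not pass (adjusted exact binomial p = 0.072). X did not differ detectably from even placement among the shared intervals (adjusted exact binomial p = 0.39). It stood at 35.8% in replicate 1 and 28.8% in replicate 2, on opposite sides of the even share, and only the value of replicate 2 passed (adjusted exact binomial p = 0.047). These tests count every peak or interval as independent, although neighbours clustered. Shared intervals merged within 10 kb had 46.5% in a centre (exact binomial p = 6.5e-12), while the values of single chromosomes are given without merging.

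**Figure D3:**
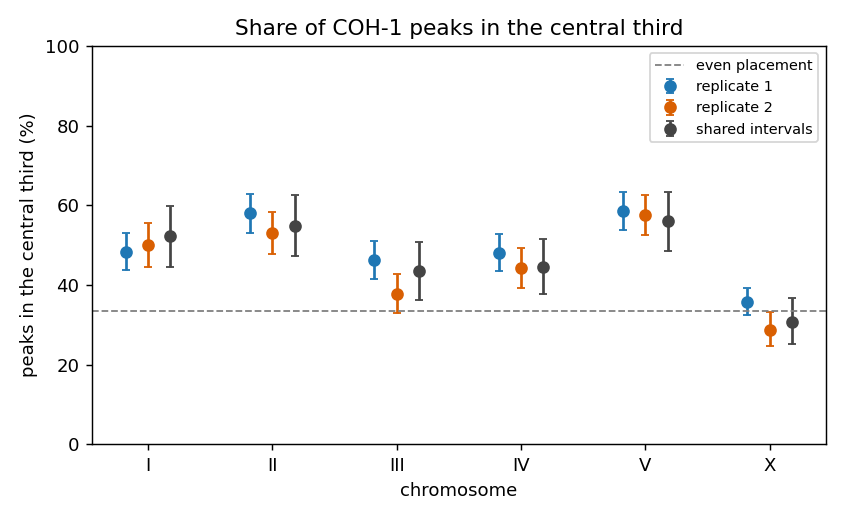
Share of peaks (%) with their midpoint in the centre of each chromosome (the middle 33.3% of its length) for replicate 1, replicate 2 and the shared intervals (points); bars are exact 95% binomial intervals and the dashed line is even placement, 33.3%. Every point of the 5 autosomes lies above the line, from 37.7% to 58.5%, and the points of X lie around it, from 28.8% to 35.8%.

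Peak numbers along the chromosomes followed each other in both lists. Across 203 bins of 500 kb, the counts of the lists had rho = 0.82 and r = 0.78 (permutation p = 1e-05 for each, the smallest possible). Bins are not independent replicates. Over the 167 autosomal bins rho was 0.85, and over the 36 bins of X it was 0.72. The bin with the most shared intervals was on I from 9000001 to 9500000, with 20 shared intervals, 48 replicate 1 peaks and 26 replicate 2 peaks. It was followed by IV from 10500001 to 11000000, with 18, and X from 4000001 to 4500000, with 17. The longest stretches without a peak in either list lay outside the chromosome centres, on V from 2730087 to 3579099 (849 kb), on IV from 14884417 to 15696508 (812 kb) and on II from 327412 to 1134241 (807 kb).

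**Figure D4:**
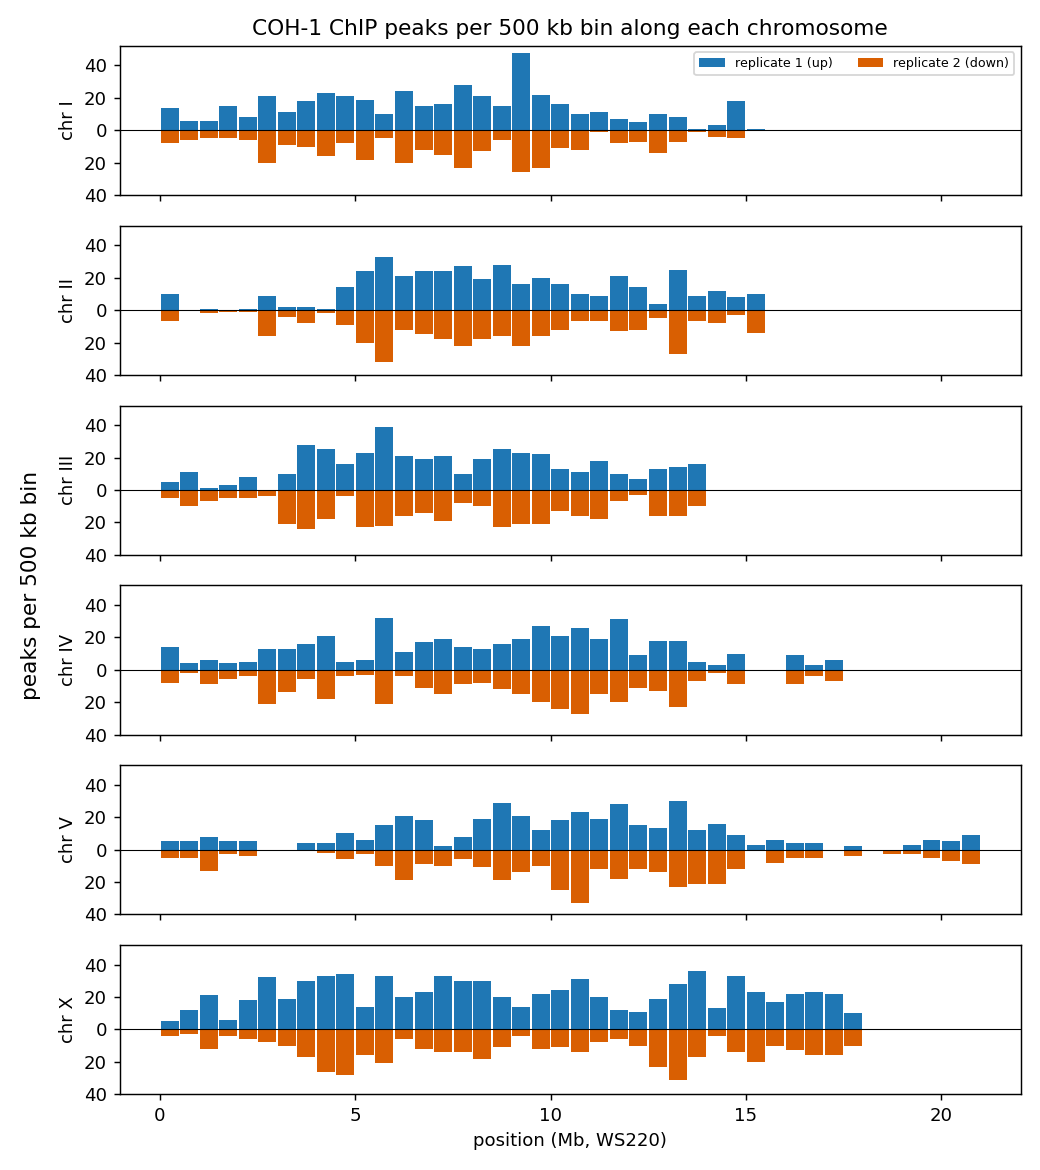
Number of COH-1 peaks per 500 kb bin (vertical axis) against position in Mb on each chromosome of build WS220 (horizontal axis), with replicate 1 drawn upwards and replicate 2 downwards. Both lists rise in the middle of the autosomes and empty out over parts of the arms of II, IV and V, and the highest bin is that on I from 9000001 to 9500000, with 48 replicate 1 peaks.

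COH-1 peaks also clustered at short range. Of the shared intervals, 63.8% had another shared interval within 10 kb between midpoints, against 21.5% for as many midpoints placed evenly at random on each chromosome (permutation test with 10000 placements, two-sided, p = 2e-04, the smallest they can give). The shares were 80.8% in replicate 1, where random placement gave 46.2%, and 86.2% in replicate 2, where it gave 37.2%. Merging shared intervals no more than 10 kb apart left 634 sites, of which 318 held a single interval and 133 held 3 or more. Those 133 sites contained 505 intervals, or 42.5% of the total. The sites with the most intervals held 7 each. They were on II from 5924159 to 5967270, on V from 8396686 to 8427547, and on X from 4481047 to 4535408, from 13313659 to 13335551 and from 15334555 to 15385239. The widest single shared interval, on V from 6208375 to 6241668, spanned 33.3 kb and consisted of 1 peak of replicate 1 and 2 of replicate 2. Random placement kept the number of midpoints per chromosome but not the concentration in the chromosome centres, which by itself brings peaks closer together. Pieces of 1 broad region called as separate peaks would also count as neighbours, and they were not told apart from separate sites. Of the 1189 shared intervals, 385 held more than 1 peak of at least 1 list.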

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

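No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, had no processed values to set against them. Over 9 results, 38 alternatives were run, and 33 kept both the direction and the side of the 0.05 threshold. The excess of shared intervals on X, a ratio of 1.31, was 1.13 with the stronger 50% of each list (exact binomial p = 0.24) and 1.20 after merging within 10 kb (exact binomial p = 0.061), both in the same direction but no longer past the threshold. Both settings leave fewer intervals and a smaller ratio, and the cause of the smaller ratio was not tested. It was 1.19 in replicate 2 alone and 1.71 in replicate 1 alone. In the strongest 10% of replicate 2 it turned to 0.78 (exact binomial p = 0.196), while in those of replicate 1 it was 1.52, and the cause was not tested. The median width of 3299 bp belongs to intervals that join peaks of both lists, against 1513 to 1564 bp over all peaks of a single list. Shared peaks before joining were already wider, with medians of 2157 bp in replicate 1 and 1922 bp in replicate 2. The share of overlapping peaks depended on the definition, from 22.6% to 54.6% of replicate 1 and from 29.1% to 76.6% of replicate 2, always above shifted lists. Against local shifts of 20 to 100 kb, which keep the large-scale density, chance overlap was 11.3% and 15.2% (permutation p = 0.002 for each, the smallest possible). Spearman's rho of the scores ranged from 0.30, with 1 peak of each list, to 0.66, under 50% reciprocal overlap. The share of shared intervals with a neighbour was 42.3% with the stronger 50% of each list, where random placement gave 11.5%, and 33.0% within 5 kb, where it gave 11.4%. The planned comparisons with gene features, gene lists and non-coding RNA classes were not run for want of an annotation of the same build. Unknown read depth keeps open whether a peak missing from 1 list was unbound or undetected.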

Other observations

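The strongest COH-1 sites did not differ detectably from the rest in how central they were. In the strongest 10% by score, 45.1% of replicate 1 peaks lay in a chromosome centre (the middle 33.3% of the length), beside 47.7% of its other peaks (Fisher's exact test, two-sided, p = 0.43). In replicate 2 the shares were 40.3% and 45.0% (Fisher's exact p = 0.19). Of the 25 strongest shared intervals, 8 were central. Of the 10 longest stretches without a peak in either list, 6 lay on V, including 17026676 to 17718560 (692 kb) and 18580016 to 19364554 (785 kb). The stretches from 2140666 to 2728998 and from 2730087 to 3579099 were parted only by a short stretch with peaks. The same held for those from 17952095 to 18571369 and from 18580016 to 19364554. These 6 are therefore not 6 separate empty regions.

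The tests that follow were chosen after the patterns had been seen. For the strongest 10% the result itself had also been seen.

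The larger X share of replicate 1 is the pattern most worth a second look, since both libraries carry the same labels. Of the peaks without a partner, 31.9% of 1535 in replicate 1 and 16.1% of 685 in replicate 2 lay on X. Of the shared peaks, 304 of 1429 in replicate 1 and 359 of 1617 in replicate 2 did. In the strongest 10%, 24.6% of replicate 1 and 14.3% of replicate 2 peaks lay on X (Fisher's exact test, two-sided, p = 0.0043). In replicate 1 that share was no higher than over the whole list, 26.8%. In replicate 2 it fell below the 20.4% of the whole list. The test therefore cannot tell by itself whether weak peaks that only the longer list holds made the difference between the whole lists. In replicate 1 the 2 weakest of the 10 score classes had 22.2% and 23.3% on X, below its whole list. Leaving out these weakest peaks would thus not lower its X share. Classes 3 and 4 had 31.4% and 30.6%, so a part played by weak peaks further up the list stays open. Sites on X broken into more pieces do not account for the whole difference. After merging within 10 kb the X shares were still 24.98% of 1145 sites in replicate 1 and 18.6% of 795 in replicate 2 (Fisher's exact p = 0.0011). These tests count sites within 1 library each, so a difference in material, in antibody recovery or in the control used for calling stays open, and so does a list that belongs to another sample. No biological explanation was tested, because the labels put both libraries in 1 group.

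The median distance from a peak without a partner to the other list was 11.6 kb for replicate 1 and 2.64 kb for replicate 2, while local shifts of 20 to 100 kb gave 29.0 kb and 21.4 kb on average (permutation p = 0.002 for each, two-sided, the smallest that 1000 shifts can give). Shifts of this length move peaks out of the regions where both lists clustered, so the p-value does not single out peaks without a partner. More than 10 kb from the other list lay 52.8% of the peaks without a partner of replicate 1 and 26.1% of those of replicate 2.

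The share of peaks in the chromosome centres was lower on X than on the autosomes in each list, with 35.8% against 51.7% in replicate 1 and 28.8% against 48.5% in replicate 2. Clusters counted many times are not the whole reason, because shared intervals merged within 10 kb gave 34.6% and 49.6% (Fisher's exact test, two-sided, p = 0.0023). Gene density and mappability along the chromosomes and a difference between X and the autosomes in COH-1 binding were not tested and stay open.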
